A study of Rattus norvegicus with 16 samples.

How the data were processed

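The material was RNA from neural stem and progenitor cells taken from the neocortex of Sprague-Dawley rats at embryonic day 14.5 and grown as a monolayer with fibroblast growth factor 2 (FGF-2) at 10 ng/ml. Cells were then kept without added growth factor, or with platelet-derived growth factor AA (PDGF-AA) at 10 ng/ml, for 12 h or 6 d. Each of the 16 arrays carried RNA of 1 of these 4 groups in one dye and RNA of FGF-2-treated cells, the common reference, in the other. Each group had 4 arrays, and the dyes were swapped on 2 of them. The labels state at least 2 independent RNA preparations behind the 4 hybridisations, but not which arrays share one. All p-values therefore measure the spread between hybridisations, which may be partly technical. Replicate numbers follow deposition order and only name an array.

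Per the labels, 40 micrograms of total RNA were labelled by reverse transcription with Cy3 or Cy5, hybridised to mouse cDNA chips with about 15000 spots, scanned with a ScanArray scanner and quantified with QuantArray. Rat RNA was thus read on mouse cDNA, and sequence differences between the species can lower or remove the signal of a spot. The deposited values are 1 log ratio per spot and array, all 16 columns being used (0 left out), taken here as log2 because the base is not given in the sources used here, and a different base would rescale every change. Background correction, normalisation within arrays and spot filters are likewise not given in the sources used here. The deposited medians lay between -0.0053 and 0.0387, so the columns lay near a common centre as deposited. Among spots that differed by over 1 unit on the Cy5 arrays of a group, 63.3% to 89.8% had the same sign on its Cy3 arrays, so the swapped arrays had already been turned to run one way. That this way is sample over reference is likely but not stated. Its basis is that genes of DNA replication lie below 0 after withdrawal of the mitogen, in a design that describes withdrawal as inducing differentiation. Every direction given here rests on it. Spot intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

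The table held 15151 features, 1 of them missing on some arrays. The mouse annotation of the chip listed a gene for 9439 features, of which 8833 had exactly 1 symbol and 606 had several. The other 5712 had no listed gene and are called unnamed probes. None of the mouse gene identifiers matched the rat gene table (0 matches), so symbols are those of the mouse annotation and no coordinates are given. Features of 1 symbol were averaged per array. Where such features disagreed in sign this is said: it held for 15 of 332 called genes with several features in no factor at 12 h and for 21 of 363 at 6 d. Features with several or no symbols were tested as they stood and never named by gene. A unit needed values on at least 3 arrays of every group, which left 12559 units, 6241 of them named genes.

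Arrays were centred on their median and fitted together with limma 3.58.1 in R 4.3.3, with a coefficient for each group and a dye term, followed by empirical Bayes moderation. Tests were two-sided, and adjusted p-values are Benjamini-Hochberg values from limma with a threshold of 0.05. The dye term mattered: 4907 units (39.1%) had a dye effect past the threshold, with a median size of 0.24 log2 units, and the dye effects estimated from the 12 h and from the 6 d arrays correlated across units at 0.662. The median correlation between arrays of one group with opposite dyes was 0.114 as deposited and 0.438 with the dye effect removed. For opposite dyes in different groups it went from 0.0118 to 0.299. Arrays of one group with the same dye went down, from 0.511 to 0.359. The dye effect was estimated on these same arrays, so these shifts partly follow from its removal. Groups were compared with the reference through the ratio against 0. The reference is treated as 1 control sample shared by all arrays, and its own spread is left out of those tests. That the same FGF-2 RNA was on every array is an assumption. Without it, differences between 12 h and 6 d and the interaction would include differences between references. PDGF-AA was compared with no factor at each time, 6 d with 12 h under each treatment, and an interaction term compared both differences.

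Gene lists, the rule for named genes, the design and the alternatives were fixed before the data were examined. The 16 lists were cell cycle and DNA replication, neural stem and progenitor, neuron, astrocyte, oligodendrocyte lineage, sterol and fatty acid synthesis, growth factor ERK feedback, immediate early, extracellular matrix and mesenchymal cell, microglia and macrophage, endothelium, glycolysis and hypoxia, stress of the endoplasmic reticulum and ATF4, p53 and cell death, cytosolic ribosomal proteins, and oxidative phosphorylation. Lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, adjusted over 117 tests, and again with the correlation estimated from the residuals. List means per array were also compared between groups by a two-sided exact permutation test of 4 against 4 arrays, whose smallest possible p is 0.0286, adjusted over 64 tests. The preset test was liberal here. In 100 draws of real residuals with random signs for PDGF-AA against no factor at 12 h, it gave p under 0.05 for 14.0% of lists and a call in 57 draws, against 1.69% and 0 draws with the estimated correlation. The 44 calls with the preset correlation became 0 with the estimated one, where the lowest adjusted p was 0.0549. In every called list the mean, the median and the test had the same direction. Camera asks whether the test statistics of list members differ from those of the other units, with the preset as the assumed correlation between members. A list call is thus only a description of members set against the other units, and member counts and the estimated p stand beside it.

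Named genes were up to 8 with the largest rise and 8 with the largest fall among those past the threshold whose arrays all lay on one side of 0, or whose groups did not overlap, plus up to 4 members of each list with the smallest p, plus a set of receptors and markers of which 7 were measured. The text summarises those that did not pass. Profiles of PDGF-AA and no factor were compared by correlation across units, with 100 simulations of unchanged groups beside it, and by the share of the no factor change seen with PDGF-AA, in which genes were picked on 1 Cy5 and 1 Cy3 array and measured on the other arrays. The fit was tested on simulated data with 200 of 12559 units changed. For no factor at 12 h against the reference it recovered 52.2% of changes of 0.5, 100% of 1 and 100% of 2 log2 units, with 7 false calls, and for PDGF-AA against no factor at 12 h 11.9%, 82.1% and 100%, with 7 false calls. Noise was drawn independently for each unit and array, without shared RNA preparations. With 200 changed units the adjusted threshold is also looser than where few units change. These shares may therefore overstate recovery in the measured data, where Rrm2 at 1.74 ± 0.31 did not pass in the direct comparison at 12 h. A simulated share of 60% at 12 h came back as 60%.

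The alternatives were no dye term, no centring, scaling arrays to a common spread, other rules on missing values, features tested singly, fits on only the groups compared, the first number of the array title as a term or as a filter, and leaving out each array. All 12 h arrays and 4 of the 6 d arrays had the same number, and the other 4, 1 without factor and 3 with PDGF-AA, had different ones. Each of those held arrays of 1 group only, and its meaning is not given in the sources used here. With the commonest number alone, PDGF-AA at 6 d had 1 array, replicate 4, which limma assumes to vary like the other groups. List results on the arrays of the commonest number, and fits without both replicate 4 arrays of 6 d, were added after seeing the data.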

Results

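Expression was measured on 16 two-colour cDNA arrays in rat neocortical neural stem and progenitor cells kept for 12 h or 6 d without growth factor or with PDGF-AA. This dimer signals through the receptor encoded by Pdgfra. There were 4 arrays in each of the 4 groups, and all were read against RNA of cells kept in FGF-2, the mitogen that maintains these cultures. Values are log2 ratios of sample over reference with standard errors from limma (n = 4 arrays per group), and 12559 genes and unnamed probes were tested. The base of the deposited log ratios, taken as 2, and their direction, likely sample over reference, are not stated, and every fold and sign below rests on them. Changes against the reference leave out the spread of the reference itself.

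After 12 h without growth factor, genes of DNA synthesis and mitosis were lower than in FGF-2. The fall of replication genes was itself the basis for reading the ratios as sample over reference, so its direction is not an independent result. Rrm2, a subunit of ribonucleotide reductase, changed by -2.66 ± 0.22 (SE), Mcm6, part of the replicative helicase, by -2.59 ± 0.23 and the DNA topoisomerase gene Top2a by -2.49 ± 0.18. Mcm3, Gmnn, which encodes the replication licensing inhibitor geminin, and the cyclin gene Ccna2 fell as well, at -2.17, -1.93 and -1.92. Sat1, an enzyme of polyamine breakdown, rose by 2.09 ± 0.27 and the growth arrest gene Gadd45g by 1.79 ± 0.25. The mitochondrial kinase gene Pink1 rose by 1.53 ± 0.27 and the matrix gene Tnc by 1.38 ± 0.20. Cdkn1c, an inhibitor of cyclin-dependent kinases, rose 2.83-fold (adjusted p = 0.023). That call was lost without replicate 1, 2 or 3 of the group, with log2 values from 1.31 to 1.76 over all single losses.

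Of 59 measured genes of cell cycle and DNA replication, 54 fell after 12 h without factor and 0 rose (56 fell when adjusted over the list alone). The list mean was -1.29 ± 0.17 (SD, n = 4). Camera called the list (adjusted p = 1.04e-60, adjusted p = 0.0552 with an estimated correlation). In sterol and fatty acid synthesis 8 of 17 fell (9 adjusted over the list alone), among them Insig1, a sterol sensor, at -0.76 and the fatty acid elongase gene Elovl6 at -0.72. The sterol list had camera adjusted p = 0.000612, and adjusted p = 0.0936 with an estimated correlation. In stress of the endoplasmic reticulum and ATF4 6 of 12 fell (8 fell and 1 rose adjusted over the list alone), including the chaperone genes Hsp90b1 at -0.93 and Calr at -0.54. That list had adjusted p = 0.000194, and adjusted p = 0.0552 with an estimated correlation. Of 27 cytosolic ribosomal protein genes 3 fell (8 adjusted over the list alone), with adjusted p = 0.000271 and adjusted p = 0.138 with an estimated correlation. The largest was the paralog Rps27l at -0.71, a gene known to respond to p53. Among 12 astrocyte genes 3 rose and 1 fell (5 and 2 adjusted over the list alone), with the glycolytic enzyme gene Aldoc at 1.29 and the metallothionein genes Mt2 and Mt1 at 0.70 and 0.68. Camera gave the astrocyte list adjusted p = 0.00664, and adjusted p = 0.360 with an estimated correlation.

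Genes known to be induced by growth factor signalling were also among those that fell at 12 h without factor. Of the 4 measured ERK feedback genes, too few for camera, 2 fell (2 adjusted over the list alone). Spry4, an inhibitor of receptor tyrosine kinase signalling, changed by -1.56 ± 0.34 and the transcription factor gene Etv5 by -1.04 ± 0.15. The immediate early gene Egr1 changed by -1.49 ± 0.23. Of 11 immediate early genes 2 fell and 1 rose (2 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.390). In all, 1468 units changed, 654 higher and 814 lower. The count was 907, 740 and 797 without replicates 1, 2 and 3 of the group and 830 without a dye term.

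With PDGF-AA for 12 h, genes of mitosis were also lower than in FGF-2. Top2a changed by -1.40 ± 0.18, the ubiquitin-conjugating enzyme gene Ube2c by -1.32 ± 0.15, and the spindle genes Tacc3 and Aspm by -1.24 ± 0.17 and -1.23 ± 0.18. Cdkn2c, an inhibitor of CDK4 and CDK6, changed by -1.20 ± 0.16. Serinc2, a membrane protein gene, rose by 1.14 ± 0.17. Of the 59 cell cycle genes 38 fell and 0 rose (46 fell adjusted over the list alone). The list mean was -0.70 ± 0.20 (SD, n = 4), with camera adjusted p = 6.22e-49, and adjusted p = 0.0720 with an estimated correlation. In sterol and fatty acid synthesis 2 of 17 fell (7 adjusted over the list alone), Dhcr7, the last enzyme of one branch of cholesterol synthesis, at -0.66 and Insig1 at -0.59, which was lost without replicate 1, 2 or 4. The sterol list at 12 h with PDGF-AA had adjusted p = 3.96e-06, and adjusted p = 0.0549 with an estimated correlation. None of the 4 ERK feedback genes passed (0, and 0 adjusted over the list alone), with Spry4 at -0.03 and Etv5 at -0.40.

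In all, 378 units changed with PDGF-AA at 12 h, 83 higher and 295 lower. The count was 76, 113 and 247 without replicates 1, 2 and 4 of the group, and 156 without a dye term. Among 8 neuron genes 1 rose (2 adjusted over the list alone), Uchl1, a ubiquitin hydrolase of neurons, at 0.50, a call lost without replicate 1 or 2. The neuron list had adjusted p = 0.00543, and adjusted p = 0.138 with an estimated correlation. In stress of the endoplasmic reticulum and ATF4 1 of 12 fell (4 fell and 1 rose adjusted over the list alone), the disulfide isomerase gene Pdia6 at -0.49. The list call (adjusted p = 0.00981, adjusted p = 0.101 with an estimated correlation) was lost without replicate 4 (adjusted p = 0.0703). No cytosolic ribosomal protein gene passed with limma (0 of 27, and 0 adjusted over the list alone), yet camera called the list. Its mean of -0.0949 (adjusted p = 0.00575, adjusted p = 0.234 with an estimated correlation) was no longer called without replicate 3 (adjusted p = 0.104).

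After 6 d without factor, Clu, which encodes a secreted chaperone, rose by 3.22 ± 0.36 and the deacetylase gene Sirt2 by 3.09 ± 0.17. Cdkn1c rose by 2.87 ± 0.41 and Igfbp5, which binds insulin-like growth factors, by 2.70 ± 0.29. The ecto-ATPase gene Entpd2 rose by 2.17 ± 0.12 and Gja1, which encodes connexin 43, by 1.89 ± 0.17. The protease inhibitor gene Cst3 fell, at -2.22 ± 0.21, as did the matrix protease gene Mmp2 at -1.80 ± 0.17. Spry4 fell as well, at -2.15 ± 0.34, with Etv5 at -1.67 ± 0.15 and Mvd, an enzyme of the mevalonate pathway, at -1.53 ± 0.24. Of 12 astrocyte genes, which include Clu, Entpd2, Gja1 and Cst3, 9 rose and 2 fell (9 and 2 adjusted over the list alone). Cst3 was among those that fell, against the direction of the list. Camera gave the list adjusted p = 8.8e-06, and adjusted p = 0.149 with an estimated correlation. All 3 measured oligodendrocyte lineage genes rose (3 adjusted over the list alone), Sirt2, the tetraspanin gene Cd9 at 0.77 and Pdgfra, the PDGF-AA receptor gene, at 1.51 ± 0.36. The Pdgfra call was lost without replicate 1 or 2.

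Cell cycle genes were below the reference at 6 d without factor as well: 43 of 59 fell and 0 rose (48 fell adjusted over the list alone), the helicase gene Mcm7 at -1.04 ± 0.09. Their mean was -0.70 ± 0.17 (SD, n = 4), with adjusted p = 1.22e-29, and adjusted p = 0.101 with an estimated correlation. Cytosolic ribosomal protein genes fell in 17 of 27 cases (22 adjusted over the list alone), with Rps20 at -0.52 and Rpl11 at -0.38. These ribosomal genes had camera adjusted p = 7.89e-14, and adjusted p = 0.0549 with an estimated correlation. In extracellular matrix and mesenchymal cell 6 of 12 rose and 1 fell (8 and 1 adjusted over the list alone), including Sparc, a matrix-binding glycoprotein, at 2.27 and Pdgfrb, the other PDGF receptor, at 1.26. That matrix list had camera adjusted p = 0.000392, and adjusted p = 0.101 with an estimated correlation. The collagen gene Col3a1 of that list stood at 1.17, but its features disagreed in sign. Among 8 neuron genes 3 rose (4 adjusted over the list alone), Mapt, which encodes tau, at 1.19 and the neuronal tubulin gene Tubb3 at 0.45. Neuron genes as a list had camera adjusted p = 0.00768, and adjusted p = 0.142 with an estimated correlation. In sterol and fatty acid synthesis 3 of 17 fell and 1 rose (3 and 1 adjusted over the list alone). The call (adjusted p = 0.0288, adjusted p = 0.155 with an estimated correlation) was lost without replicate 2 (adjusted p = 0.114). Of the ERK feedback genes 3 of 4 fell (3 adjusted over the list alone), and the progenitor filament gene Nes changed by -0.89 ± 0.12.

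No factor at 6 d had the highest count of the 4 groups on all arrays. Without replicate 1, 2 or 3 of that group, the count was higher for no factor at 12 h. In all, the count at 6 d without factor was 1723 units, 878 higher and 845 lower. It was 1012 and 1018 without replicates 1 and 3 of the group, 990 without a dye term, and 1132 on the arrays that share the commonest first number in their titles.

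With PDGF-AA for 6 d, Sirt2 rose by 2.63 ± 0.17, the kinase gene Sgk1 by 1.98 ± 0.22, and Tmcc2 by 2.21 ± 0.28. Pdgfa, which encodes the chain that forms PDGF-AA, rose by 1.72 ± 0.15 and stood at 1.82 ± 0.15 without factor. Cst3 and Mmp2 fell, at -2.06 ± 0.21 and -1.83 ± 0.17, as did Etv5 at -1.15 ± 0.15, the BMP target gene Id1 at -1.02 ± 0.18 and Nes at -0.83 ± 0.12. Of the 59 cell cycle genes 3 fell and 0 rose (16 fell adjusted over the list alone). Their mean of -0.30 ± 0.36 (SD, n = 4) had adjusted p = 1.06e-11, and adjusted p = 0.294 with an estimated correlation. Replicate 4 lay lowest for these genes, at -0.748 against -0.347 to 0.113 on the other arrays. Of 12 astrocyte genes 3 rose and 2 fell (4 and 2 adjusted over the list alone). Gja1 at 1.20 ± 0.17 and Entpd2 at 0.72 ± 0.12 were among those that rose, and Cst3 among those that fell. Camera did not call the astrocyte list (adjusted p = 0.109, adjusted p = 0.630 with an estimated correlation), but did so without replicate 1 of PDGF-AA at 6 d (mean 0.271, adjusted p = 0.0323) and with the title number as a term (0.361, adjusted p = 0.0439). The mean of 0.166 on all 4 arrays rests on replicate 4, at 0.787 against -0.123 to 0.0404 on the other arrays.

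Of the 3 oligodendrocyte lineage genes 2 rose with PDGF-AA at 6 d (3 adjusted over the list alone). Among the 4 ERK feedback genes 2 fell (3 adjusted over the list alone), Etv5 and Spred2, an inhibitor of ERK signalling, at -0.77 ± 0.11. In extracellular matrix and mesenchymal cell 3 of 12 rose (7 adjusted over the list alone), with Col3a1 at 1.04. Matrix genes as a list had camera adjusted p = 2.91e-06, and adjusted p = 0.0720 with an estimated correlation. Glycolysis and hypoxia had 2 of 13 genes higher (3 adjusted over the list alone). That call (adjusted p = 0.0165, adjusted p = 0.166 with an estimated correlation) was lost without replicate 3 (adjusted p = 0.0946) and with the title number as a term (0.120). No ribosomal protein gene passed with limma (0 of 27, 4 fell adjusted over the list alone), while the list mean of -0.149 was called (adjusted p = 8.8e-06, adjusted p = 0.101 with an estimated correlation). In all, 404 units changed, 238 higher and 166 lower. The count was 157 and 225 without replicates 2 and 4 of the group, 191 without a dye term, and 622 with arrays scaled to a common spread. It was 28 when only this group was fitted, 31 with the title number as a term, 175 on the arrays of the commonest title number (1 with PDGF-AA at 6 d), and 239 without both replicate 4 arrays of 6 d.

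**Figure D1:**
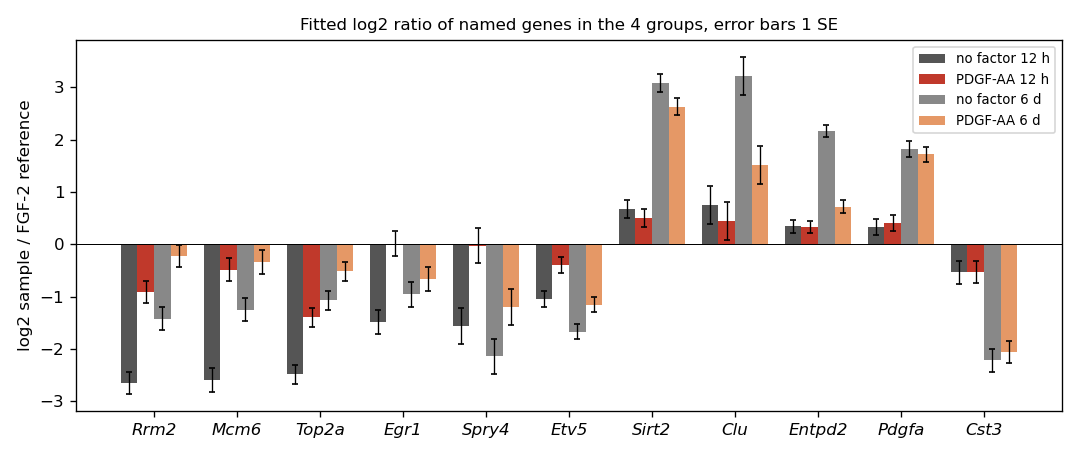
Fitted log2 ratio to the FGF-2 reference (vertical axis) of 11 named genes (horizontal axis) in the 4 groups, with bars for group values and error bars of 1 SE (4 arrays per group). Rrm2, Mcm6 and Top2a lie lowest at 12 h without factor, and Sirt2 and Clu lie highest at 6 d without factor, at 3.09 and 3.22.

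The lists of other cell types and stresses were tested in the same way against the reference. None of 6 microglia and macrophage genes and none of 4 endothelium genes passed in any group with limma (0, and 0 adjusted over the list alone). The group means of these lists lay between -0.0427 and 0.0490. Of 7 genes in p53 and cell death, Ccng1, a p53 target gene, changed by -0.60 ± 0.10 at 12 h without factor, where 1 gene rose and 1 fell (1 and 1 adjusted over the list alone). Camera called this list in no group (lowest adjusted p = 0.505). Of 57 oxidative phosphorylation genes at most 3 passed in a group (3 adjusted over the list alone), with Sdhd, a subunit of succinate dehydrogenase, at -0.53 ± 0.11 at 12 h without factor. The lowest camera adjusted p of that list was 0.188. Of 15 neural stem and progenitor genes, at 6 d without factor 2 rose and 5 fell (2 and 7 adjusted over the list alone), with Tnc at 1.75 and Nes at -0.89. Camera gave adjusted p = 0.0563 (adjusted p = 0.138 with an estimated correlation), and with the preset correlation called the list when only this group was fitted (adjusted p = 0.0125) and on the arrays of the commonest title number (adjusted p = 0.0289). It also did so, at adjusted p from 0.0297 to 0.0481, without replicate 1 or 4 of PDGF-AA at 12 h, replicate 2 of no factor at 6 d, or replicate 2 or 3 of PDGF-AA at 6 d.

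The direct comparison asked how far PDGF-AA in place of no factor altered expression at 12 h. Mcm6 was the named gene that passed, higher with PDGF-AA by 2.11 ± 0.32 (adjusted p = 0.033), from -2.59 without factor to -0.49 with PDGF-AA, with no overlap between the groups' arrays. The unnamed probe H3021F12_1, chosen after its values were seen, differed by 1.31 ± 0.20 (adjusted p = 0.033). Of the 59 cell cycle genes 1 passed over all genes tested and 27 were higher adjusted over the list alone. The list mean was higher by 0.583, with adjusted p = 3.6e-34, and adjusted p = 0.101 with an estimated correlation. The exact permutation p was 0.0286, or 0.131 adjusted. Egr1 stood 2.82-fold higher and Spry4 1.53 ± 0.48 higher, and neither passed (adjusted p = 0.253 and 0.719). ERK feedback had 0 of 4 over all genes and 2 higher adjusted over the list alone, with a mean difference of 0.559 (exact permutation p = 0.0286, adjusted 0.131).

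The astrocyte mean differed by -0.221 with PDGF-AA at 12 h, with 0 of 12 past the threshold in limma and 1 lower adjusted over the list alone. Camera gave adjusted p = 0.0358, and adjusted p = 0.482 with an estimated correlation. That call was lost without replicate 2 of no factor (adjusted p = 0.240) and replicates 1, 2 and 3 of PDGF-AA (adjusted p = 0.0597, 0.0536 and 0.132). Stress of the endoplasmic reticulum and ATF4 was higher by 0.189, with 0 of 12 genes past the threshold and 0 adjusted over the list alone (adjusted p = 0.00664, adjusted p = 0.101 with an estimated correlation). In all 2 units passed, both higher, and 681 had an unadjusted p under 0.05. Both were lost (0 units) without replicate 1, 2 or 3 of no factor at 12 h, replicate 2, 3 or 4 of PDGF-AA at 12 h, or replicate 2 or 3 of no factor at 6 d. Mcm6 was also lost without replicate 1 of PDGF-AA at 12 h (1 unit). The count was 5 and 8 without replicates 1 and 4 of PDGF-AA at 6 d, 0 without a dye term or with scaled arrays, 25 when only these groups were fitted, and 9 without both replicate 4 arrays of 6 d.

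At 6 d, Entpd2 was the 1 unit that differed between PDGF-AA and no factor, at -1.45 ± 0.17 (adjusted p = 0.002), from 2.17 to 0.72, and this call held without any single array. Of 12 astrocyte genes 1 passed over all genes and 7 were lower adjusted over the list alone, with a mean difference of -0.591. Camera gave adjusted p = 4.47e-08, and adjusted p = 0.101 with an estimated correlation. Cell cycle genes were higher by 0.405, with 0 of 59 past the threshold over all genes and 2 adjusted over the list alone (adjusted p = 6.92e-17, adjusted p = 0.191 with an estimated correlation). For both lists the exact permutation p was 0.0857, or 0.229 adjusted. The neuron mean differed by -0.306, with 0 of 8 and 2 adjusted over the list alone (adjusted p = 0.00353, adjusted p = 0.131 with an estimated correlation). Cytosolic ribosomal protein genes were higher by 0.193, with 0 of 27 and 0 adjusted over the list alone (adjusted p = 6.36e-07, adjusted p = 0.1 with an estimated correlation).

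The PDGF-AA arrays of 6 d differed among themselves in these groups. Replicate 4 had an astrocyte mean of 0.787, a cell cycle mean of -0.748 and a neuron mean of 0.265, against -0.123 to 0.0404, -0.347 to 0.113 and -0.128 to 0.0618 on the other PDGF-AA arrays. No factor arrays spanned 0.461 to 1.05, -0.876 to -0.534 and 0.254 to 0.43. Replicate 4 is also the only PDGF-AA array of 6 d with the commonest title number. Among arrays with that number, 1 with PDGF-AA and 3 without factor, the difference was 0.128 for astrocyte, -0.103 for cell cycle, 0.203 for ribosomal protein and -0.0541 for neuron genes. Among the others, 3 and 1 with different numbers in each group, it was -1.09, 0.728, 0.179 and -0.464. With the title number as a term the differences were -0.461, 0.294, 0.191 and -0.25. The 0.128 and -0.103 above take the dye effect from all arrays. A fit of only the arrays with the commonest number gave 0.155 for astrocyte and -0.134 for cell cycle genes. At 6 d 1100 units had an unadjusted p under 0.05. The count of calls was 58 without replicate 4 of PDGF-AA, 2 without replicate 1 of PDGF-AA or with scaled arrays, and 0 without a dye term or with only these groups fitted. Without both replicate 4 arrays, a choice made after the values were seen, it was 229 (56 higher, 173 lower).

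**Figure D2:**
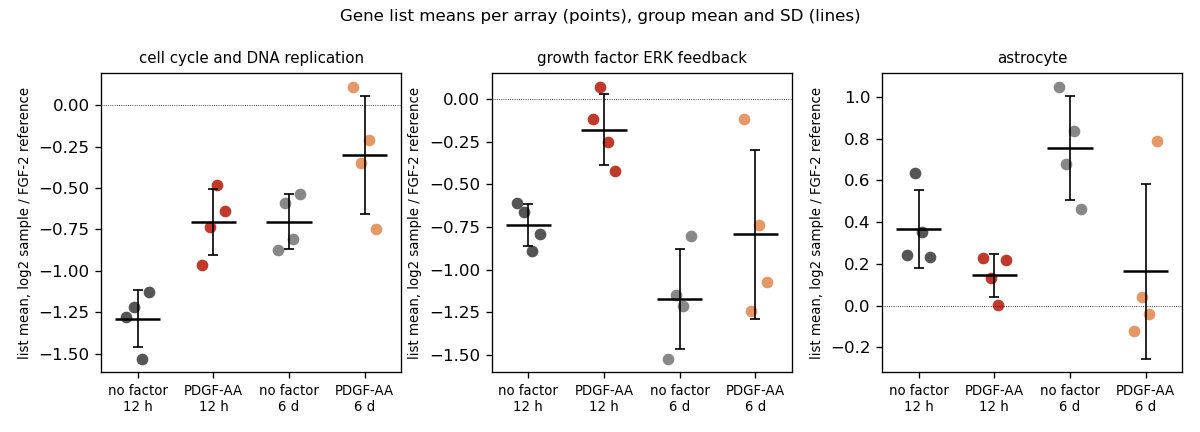
Mean log2 ratio to the FGF-2 reference (vertical axis) of 3 gene lists on each array (points) in the 4 groups (horizontal axis), with the group mean and SD as lines and the dye effect removed. Cell cycle means lie between -1.53 and -1.13 at 12 h without factor, and the PDGF-AA group at 6 d has the widest spread for this list, from -0.748 to 0.113.

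From 12 h to 6 d without factor, several genes rose: Sirt2 by 2.42 ± 0.24, the transmembrane protein gene Itm2a by 1.90 ± 0.24, Entpd2 by 1.83 ± 0.17 and Gja1 by 1.56 ± 0.23. Mmp2 and Cst3 fell, at -1.79 ± 0.25 and -1.68 ± 0.30, as did Smoc1, a calcium-binding matrix protein gene, at -1.54 ± 0.22. Cell cycle genes were nearer the reference at 6 d, with 11 of 59 higher and 0 lower (31 higher adjusted over the list alone). Examples were Top2a by 1.42 ± 0.26 and the DNA ligase gene Lig1 by 1.09 ± 0.20. The list mean was 0.585 higher, with adjusted p = 1.16e-21, and adjusted p = 0.138 with an estimated correlation. Ribosomal protein genes were lower, with 1 of 27 past the threshold and 2 adjusted over the list alone (adjusted p = 2.67e-05, adjusted p = 0.101 with an estimated correlation). Extracellular matrix and mesenchymal cell (1 of 12 rose, 6 rose and 1 fell adjusted over the list alone), glycolysis and hypoxia (2 of 13, 4 and 1) and stress of the endoplasmic reticulum and ATF4 (2 of 12, 4 and 0) were higher. In that order they had adjusted p = 0.00188, 0.00873 and 0.00981, and adjusted p = 0.132, 0.138 and 0.101 with an estimated correlation.

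The astrocyte list rose in 3 of 12 genes and fell in 1, Cst3 (4 and 2 adjusted over the list alone). The call (adjusted p = 0.0165, adjusted p = 0.411 with an estimated correlation) was lost without replicate 1 of no factor at 6 d (adjusted p = 0.0887), on the arrays of the commonest title number (0.241) and with only these groups fitted (0.0706). In all 235 units changed over time without factor, 178 higher and 57 lower. The count was 111, 143, 112 and 125 without replicates 1 to 4 of the 12 h group, and 112 and 141 without replicates 3 and 4 of the 6 d group. It was 87 without a dye term and 143 with the title number as a term.

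From 12 h to 6 d with PDGF-AA, Sirt2 rose by 2.13 ± 0.24, the cytoskeletal linker gene Epb41l2 by 2.07 ± 0.17 and Sgk1 by 2.04 ± 0.32. The semaphorin gene Sema6d rose by 1.59 ± 0.19, and Mmp2 fell, at -1.59 ± 0.25. In sterol and fatty acid synthesis 2 of 17 rose (4 adjusted over the list alone). Hmgcs1, an early enzyme of the mevalonate pathway, rose 2.14-fold, a call lost without replicate 1, 2 or 4 of PDGF-AA at 12 h or replicate 1, 2 or 3 at 6 d. The list call (adjusted p = 0.00664, adjusted p = 0.106 with an estimated correlation) was lost without replicate 3 of PDGF-AA at 6 d (adjusted p = 0.0567) and with the title number as a term (0.115). Cell cycle genes were higher by 0.406, with 1 of 59 past the threshold and 9 adjusted over the list alone (adjusted p = 2.73e-12, adjusted p = 0.278 with an estimated correlation). They stood at -0.0899 on the arrays of the commonest title number, where replicate 4 is the only PDGF-AA array of 6 d. Extracellular matrix and mesenchymal cell (0 of 12, 1 adjusted over the list alone) and glycolysis and hypoxia (0 of 13, 3 adjusted over the list alone) were higher with PDGF-AA over time. They had adjusted p = 0.00114 and 0.000612, and adjusted p = 0.120 and 0.101 with an estimated correlation. The first was lost with the title number as a term (adjusted p = 0.115).

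Immediate early genes were lower over time with PDGF-AA, with 0 of 11 past the threshold in limma and 2 adjusted over the list alone (mean -0.213, adjusted p = 0.0475, adjusted p = 0.341 with an estimated correlation). On the arrays of the commonest title number, with replicate 4 as the only PDGF-AA array of 6 d, the mean was 0.0935. The call was lost with the title number as a term (adjusted p = 0.801) and, at adjusted p from 0.0502 to 0.152, without replicate 2 of no factor at 12 h or at 6 d, replicate 1, 2 or 4 of PDGF-AA at 12 h, or replicate 1, 2 or 3 of PDGF-AA at 6 d. In all 135 units changed, 80 higher and 55 lower. The count was 64, 65 and 85 without replicates 1, 2 and 4 of the 12 h group, 48 and 211 without replicates 2 and 4 of the 6 d group, and 38 without a dye term. It was 21 with only these groups fitted, 9 with the title number as a term, 11 on the arrays of the commonest title number, and 259 without both replicate 4 arrays of 6 d.

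Whether the PDGF-AA difference itself changed between 12 h and 6 d was tested with the interaction term. No unit passed with limma (0 units, lowest adjusted p = 0.181), and 497 had an unadjusted p under 0.05. The changes with PDGF-AA and without factor nevertheless ran together across units, with a Pearson correlation of 0.689 at 12 h and 0.608 at 6 d (Spearman 0.464 and 0.418, covariance 0.0399 and 0.0425). These are correlations across genes, which are not independent replicates, and 100 simulations of unchanged groups gave correlations of 0 and -0.001 and a covariance of 0. The simulated groups were drawn independently, without a shared reference. Values near 0 therefore follow from the setup and give no baseline for what the reference contributes. The correlation at 12 h was 0.651 without replicate 1 of no factor, and 0.576 and 0.622 without replicates 1 and 3 of PDGF-AA. The correlation at 6 d was 0.555 without replicate 4 of no factor, and 0.539 and 0.472 without replicates 3 and 4 of PDGF-AA.

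Of the units higher with PDGF-AA at 12 h, 76 of 83 were also higher without factor, where independent lists would share 4.32, and of the lower ones 263 of 295, against 19.1. At 6 d the overlaps were 221 of 238 higher (16.6) and 124 of 166 lower (11.2), and 0 units were called in opposite directions at either time. Part of the correlation and overlap may come from the reference shared by all arrays. For genes picked on separate no factor arrays, PDGF-AA showed 60.3% of the no factor change at 12 h (53.2% to 66.7% over the ways of choosing the arrays) and 71.2% at 6 d (60.3% to 82.8%). The 6 d share ranged from 51.6% without replicate 4 of no factor to 87.1% without replicate 1 of PDGF-AA, and was 58.9% without replicate 4 of PDGF-AA.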

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

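The tests on the 6 d arrays below were chosen after the result was seen, while the counts over other splits of the arrays were planned. For the 4 groups against the reference, turning the signs of the arrays gives 8 patterns, too few for a share under 0.05. The real count was 1468 against a highest other count of 0 for no factor at 12 h, 378 against 0 for PDGF-AA at 12 h, 1723 against 0 for no factor at 6 d and 404 against 21 for PDGF-AA at 6 d, with 1 pattern as large in each case, the real one. For 6 d against 12 h, 1 of 35 splits was as large without factor (235, highest other 0) and 1 of 35 with PDGF-AA (135, highest other 1). In each case it was the real split. The splits treat all arrays as independent, which arrays that share an RNA preparation are not, so these shares cannot exclude chance. With PDGF-AA most 6 d arrays also had other title numbers than the 12 h arrays, and the count fell with that number as a term. For PDGF-AA against no factor the real count did not stand out: 2 of 35 splits were as large at 12 h (2 units, highest other 2) and 2 of 35 at 6 d (1 unit, highest other 277). For the interaction all 100 of 100 drawn splits were as large as the real count of 0, with a highest other of 376.

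The 6 d split with 277 units exchanges replicate 4 of PDGF-AA with replicate 4 of no factor, and a count so far above the real one points to a structure of these arrays: placed between the mean of no factor (0) and that of PDGF-AA (1) on genes chosen without the array, PDGF-AA replicates 1 to 4 lay at 0.598, 0.758, 0.329 and 0.0562 and no factor replicates 1 to 4 at 0.0941, 0.349, 0.364 and 0.750. A shift common to the arrays without the commonest title number, a shift of its own for each number and a shared RNA preparation stay open: the differences that a common shift predicts to run together correlated at -0.188 across units, but that value rests on 1 no factor array, the only one of 6 d without the commonest number. A single wrong label for replicate 4 of PDGF-AA cannot be told apart from spread, because at 0.0562 it lies below the highest no factor array, as PDGF-AA replicates 1 and 3 do. An exchange of both replicate 4 labels stays open, with values on either side: with both held out, the no factor array lay 0.499 further towards PDGF-AA than the PDGF-AA array, the highest of 16 pairs (next 0.205), and 229 units were called without both against 0 to 6 without any of the other 15 pairs, but the pair was picked by the split itself, so these values are not independent evidence. Of those 229 units both arrays lay nearer the other group for 141 and nearer the group of their label for 5. For 69 both lay nearer no factor, and for 14 both lay nearer PDGF-AA. Entpd2 was among the 5 (0.80 on the PDGF-AA array, others 0.49 to 0.85, and 2.00 on the no factor array, others 1.98 to 2.64). Of the 16 lists the ribosomal protein means of both (-0.143 and -0.37) lay with their label (others -0.229 to -0.0687 and -0.429 to -0.238). Those of stress of the endoplasmic reticulum and ATF4 lay with the other group. The remaining lists placed both arrays in neither way. A real difference between cultures stays untested.

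In 13 of 156 groups of 4 arrays, 1 array lay far from the other 3, where chance gives about 1 in 20 groups, or 7.8. On replicate 3 of PDGF-AA at 12 h these were the immediate early mean (-0.26, others 0.12 to 0.18), the ribosomal protein mean (-0.20, others -0.07 to -0.05), Aspm (-0.62, others -1.46 to -1.42) and Nusap1, a spindle gene (-0.41, others -1.47 to -1.36). At 12 h without factor replicate 4 stood apart for Serinc2 (1.27, others 1.94 to 2.01) and Pink1 (0.93, others 1.64 to 1.78). At 6 d without factor it was replicate 4 for Nrbp2 (1.22, others 2.51 to 2.65) and Mvd (-2.87, others -1.16 to -0.95), replicate 1 for Entpd2 (2.64, others 1.98 to 2.05) and Etv5 (-2.09, others -1.55 to -1.52), and replicate 2 for Itm2a (1.63, others 2.19 to 2.29). With PDGF-AA at 6 d it was replicate 3 for p53 and cell death (-0.12, others 0.12 to 0.16) and replicate 1 for Sirt2 (2.05, others 2.74 to 2.88).

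The difference between PDGF-AA and no factor changed from 12 h to 6 d for 6 lists in camera with the preset correlation and for none with the estimated one, and in each no gene passed with limma (0 units over all genes, 497 at an unadjusted p under 0.05). The neuron list had an interaction of -0.363 (adjusted p = 0.00114, adjusted p = 0.101 with an estimated correlation), a call that held without any single array, although the mean of replicate 4 of PDGF-AA at 6 d (0.265) lay among the no factor arrays (0.254 to 0.43) and not among the other PDGF-AA arrays (-0.128 to 0.0618). The astrocyte list had -0.370 (adjusted p = 0.00315, 0.341 estimated) and immediate early -0.303 (adjusted p = 0.00981, 0.213 estimated), lost without replicate 3 of PDGF-AA at 6 d (adjusted p = 0.0632 and 0.0682) and with the title number as a term (0.115 and 0.217). Ribosomal proteins had 0.115 (adjusted p = 0.00952, 0.269 estimated), lost without replicate 3 of PDGF-AA at 12 h, of no factor at 6 d or of PDGF-AA at 6 d (adjusted p = 0.0519, 0.0845 and 0.0848) and with the title number as a term (0.0519). The cell cycle list had -0.179 (adjusted p = 0.0119, 0.707 estimated), lost without replicate 3 of no factor at 12 h (0.364) or 3 or 4 of PDGF-AA at 12 h (0.390 and 0.0675). It was also lost without replicate 2 or 4 of no factor at 6 d (0.0916 and 0.184) or 4 of PDGF-AA at 6 d (0.982). With arrays scaled to a common spread it fell to -0.0576 (adjusted p = 0.615), and without both replicate 4 arrays of 6 d it was 0.0686 (0.236). Oxidative phosphorylation had 0.0782 (adjusted p = 0.0305, 0.459 estimated), lost without replicate 1, 2 or 3 of no factor at 12 h (0.0555, 0.0963 and 0.0675) or 3 of PDGF-AA at 12 h (0.219). It was lost, too, without replicate 3 of no factor at 6 d (0.134) or 3 or 4 of PDGF-AA at 6 d (0.0848 and 0.263), with scaled arrays (0.0631) and without both replicate 4 arrays of 6 d (0.314).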

How the results depend on the processing

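Fits with both replicate 4 arrays of 6 d left out, and list means on the arrays of the commonest title number, were chosen after seeing the data, and the other alternatives were planned. Filters on missing values and the deposited scale without centring kept every count within 1.5 times. They could change little, since 1 feature had missing values and the deposited medians lay near 0. Without a dye term the counts were 830 and 156 at 12 h and 990 and 191 at 6 d (no factor, then PDGF-AA, against the reference), 0 and 0 for PDGF-AA against no factor at 12 h and 6 d, and 87 and 38 for 6 d against 12 h without factor and with PDGF-AA. Scaling the arrays gave 622 for PDGF-AA at 6 d and 0 and 2 for the direct comparisons at 12 h and 6 d. With only the groups compared, the counts were 28 for PDGF-AA at 6 d, 25 and 0 for the direct comparisons, and 21 for PDGF-AA over time. The title number as a term gave 31 for PDGF-AA at 6 d and 143 and 9 over time. The arrays of the commonest title number alone, being fewer (1 with PDGF-AA at 6 d), gave 1132 and 175 at 6 d and 11 for PDGF-AA over time. Without both replicate 4 arrays the counts were 239 for PDGF-AA at 6 d, 9 and 229 for the direct comparisons and 259 for PDGF-AA over time. The estimated correlation gave 0 called lists in place of 44. The 6 d share was 59.6% with genes picked at 0.5 log2 units. Leaving out 1 array gave 740 to 1564, 76 to 489, 1012 to 1802 and 157 to 461 against the reference (no factor and PDGF-AA at 12 h, then 6 d), 0 to 8 and 1 to 58 for the direct comparisons, 111 to 300 and 48 to 211 over time, 0 to 0 for the interaction, 39 to 47 called lists, correlations of 0.576 to 0.691 and 0.472 to 0.625, and shares of 56.0% to 64.7% and 51.6% to 87.1%.

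Directions turned in few cases. On the arrays of the commonest title number, replicate 4 is the only one with PDGF-AA at 6 d and is assumed to vary like the other groups, so the list values turned there describe that array, and their p-values measure no spread of its group. The list means were 0.138 for oxidative phosphorylation with PDGF-AA at 6 d (adjusted p = 0.0472), -0.134 and 0.155 for cell cycle and astrocyte in the direct comparison at 6 d (0.0405 and 0.354), and -0.0899 and 0.0935 for cell cycle and immediate early over time with PDGF-AA (0.0977 and 0.721). The astrocyte mean over time with PDGF-AA was 0.683 there (0.000504), where all arrays gave 0.0213 and a test that pointed lower (0.981). The cell cycle interaction was 0.0686 without both replicate 4 arrays (0.236) and lost its call with scaled arrays (-0.0576, 0.615), as did that of oxidative phosphorylation (0.0632, 0.0631), while Col3a1 in no factor at 6 d was -0.04 on 1 of its features tested singly, and Fgfr1 with PDGF-AA at 6 d was -0.63 without replicate 3. Fewer arrays enter where some are left out, and beyond that the cause was not tested. Of the list results without 1 array, 1810 kept their side of the threshold, 36 lost a call and 26 gained one, and of those of named genes 10274, 326 and 87. No paired analysis was possible because replicate numbers follow deposition order and pair no arrays. The array titles also hold a second number, which was not used. At 12 h its neighbouring values include pairs of arrays of the same group with opposite dyes. Whether such arrays share an RNA preparation is not stated and was not tested. If they do, each group holds fewer independent samples than arrays. Signal over background is unknown, so a dim spot cannot be told from a bright one.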

Other observations

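The gene families, the phase lists and the tests on them below were chosen after the data were seen. Adjusted p-values do not cover that choice. Glutathione S-transferases, enzymes that conjugate glutathione, had means above the reference in both conditions. Most of the 9 measured were Gstm genes. Gsto1 and Gstp3 stayed near the reference without factor, at 0.12 and -0.01 at 12 h and -0.04 and 0.02 at 6 d. Without factor 6 of 9 rose at 12 h (mean 0.68, camera adjusted p = 4.15e-06 over 126 tests, adjusted p = 0.103 with an estimated correlation). At 6 d 6 of 9 rose (mean 0.80, adjusted p = 3.06e-06, adjusted p = 0.103 with an estimated correlation), with Gstm1 at 1.93 and Gstm2 at 1.25. With PDGF-AA 3 of 9 rose at 12 h and 3 at 6 d (means 0.39 and 0.48, adjusted p = 0.00028 and 4.85e-05, adjusted p = 0.178 and 0.134 with an estimated correlation). Cathepsins, proteases of the lysosome, rose in 4 of 6 cases without factor at 6 d, with Ctsa, which encodes a lysosomal carboxypeptidase, at 1.12, Ctsl at 1.07 and Ctsd at 0.91 (adjusted p = 2.63e-05, adjusted p = 0.131 with an estimated correlation). The cathepsin mean was lower with PDGF-AA than without factor at 6 d by -0.51, with 0 of 6 genes past the threshold in limma (adjusted p = 4.06e-06, adjusted p = 0.103 with an estimated correlation).

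Mitochondrial ribosomal protein genes fell in 14 of 46 cases without factor at 6 d, with a mean of -0.21. Camera gave adjusted p = 2.51e-06, and adjusted p = 0.029 with an estimated correlation. Because this family was picked after the data were seen, neither value is an independent test. With PDGF-AA at 6 d 0 of 46 passed in limma (mean -0.06, adjusted p = 0.0273, adjusted p = 0.155 with an estimated correlation). In the direct comparison of PDGF-AA with no factor at 6 d none of these genes passed, Entpd2 being the 1 unit called. The unnamed probe H3152H08_1, chosen after its values were seen, stood at 6.18 ± 0.29 (72.3-fold) without factor at 6 d and at 5.22 ± 0.29 (37.4-fold) with PDGF-AA.

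Within the cell cycle, 29 replication and 44 mitotic genes, which overlap the cell cycle list of the report, were compared in how far PDGF-AA moved them. At 12 h replication genes averaged -1.02 without factor and -0.40 with PDGF-AA, and mitotic genes -1.14 and -0.81. The replication mean minus the mitotic mean was 0.41 ± 0.05 (SD, n = 4) with PDGF-AA and 0.12 ± 0.13 without factor, a difference of 0.29 (from 0.22 to 0.31 without any single array) that did not pass after adjustment over both times (exact permutation p = 0.0286, the smallest possible, 0.0572 adjusted), and at 6 d it was 0.05 (exact permutation p = 0.629, 0.629 adjusted). At 12 h an equal share in both lists predicts a replication mean minus mitotic mean of 0.07 on the PDGF-AA arrays. These lay 0.34 above it (0.27 to 0.37, against an SD of 0.09 between arrays of both groups). The values argue against an equal share on these arrays only. The rule was set on them after the values were seen, and shared RNA preparations could make that SD partly technical. At 6 d the excess of 0.11 (-0.14 to 0.29, SD 0.19) leaves an equal share open. PDGF-AA showed 39.4% of the fall for replication and 70.9% for mitotic genes at 12 h (31.6 points, 95% interval 23.8 to 39.0), and 29.7% and 50.5% at 6 d (20.8 points, 8.51 to 33.1), with intervals from bootstraps of genes, which are not independent and leave out the spread between arrays; a shift of the balance towards replication transcripts stays open as a hypothesis at both times, and cell counts per phase were not used here.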
